A study of Mus musculus with 32 samples.

How the data were processed

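The deposited tables held whole-number UMI counts per cell and gene for 32 libraries, 2 per group, made by the authors from droplet libraries of the 3' ends of transcripts (ddSEQ, SureCell kit), per the labels. Reads were demultiplexed with bcl2fastq 2.19 and aligned with STAR to mm10, per the submitters' processing notes. The annotation and the counting program are not given in the sources used here. Barcodes had passed a knee filter, and a second deposited table listed barcodes the authors called irradiated feeder MEFs. Per the labels, doxycycline was at 2 ug/mL, ascorbic acid at 50 ug/mL and SGC0946 at 5 uM, and 2i was added 12 h after these. The feeder table has 2 further columns, naming treatment and time point, which were not used here.

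Of 8334 barcodes, 684 on the feeder list were left out and 7650 kept. The tables held 24421 genes, of which 18897 had a UMI, and no mitochondrially encoded gene. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom from 1.64 to 8.62 and a correlation of log2 CPM across genes from 0.955 to 0.993, so none was counted as a copy. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which can be technical.

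UMI counts were summed over the kept cells of each library and tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr) in R 4.3.3, in one fit of all 32 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. There were 15 comparisons and 3 interactions. SEs were computed from the fold change and the test statistic. CPM levels are library means of summed counts, scaled with TMM factors. Levels of Eif4a1, Acp1, Ccnb1ip1 and Y-linked genes were scaled to library totals instead. Of 30 gene lists fixed before the data were examined, the 27 with at least 3 tested genes were run through camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The rule for genes to name was also fixed before the data were examined. It took, per comparison, the 6 called genes with the most positive and the 6 with the most negative fold change at 50 CPM or more in the higher group, with no overlap between libraries and without mitochondrial, ribosomal-protein, predicted and Rik genes. It added a panel of 15 marker genes and up to 2 called list members each way, or the 2 of smallest p. A part of the genes and lists the rule gave is described, chosen for length after values were seen. Positions are from the GENCODE mouse annotation of this build.

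Cells with a UMI were counted after thinning each cell to 1000 UMIs. No test of shares was planned or run. An exact permutation test of 2 against 2 libraries allows no p under 0.333, and no model of shares over all libraries was fitted. Clustering in scanpy 1.11.5 (Python 3.11.15, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1) gave 16 clusters, and since some held more markers of another class than of their own, no class was compared. Scrublet called 270 cells (3.53%) doublets, which were kept. Further tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

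On data simulated for A2 day 6 against A2S day 6, over 12183 genes, the test called 33.8% of 65 genes changed by 1.5-fold, 64.6% of 65 changed by 2-fold and 93.5% of 62 changed by 4-fold, with 7 false among 129 calls. Alternatives were RLE factors, no count filter, DESeq2 1.42.0, the replicate letter as a block, listed cells kept, cells of 1000 UMIs or more, a fit of the compared groups alone and each library left out in turn. For shares, thinning to 500 or 2000 UMIs or none was tried. Comparisons among A2, S2 and AS were added after the data were seen. FBS day 9 was summed with the rest but entered no comparison.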

Results

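Single-cell 3' RNA counts were analysed from 32 libraries of mouse cells, in 16 groups of 2. Mouse embryonic fibroblasts (MEFs) were reprogrammed with doxycycline, either in serum medium without small molecules (FBS, days 3, 6, 9 and 12) or with ascorbic acid, 2i and SGC0946, a DOT1L inhibitor (A2S, days 2, 4 and 6). The 2i pair joins CHIR-99021, a GSK3 inhibitor, to PD-0325901, a MEK inhibitor. In 3 further media, sampled at days 4 and 6, a part of A2S was left out: A2 lacked SGC0946, S2 lacked ascorbic acid and AS lacked 2i. Untreated MEFs, embryonic stem cells (ESCs) and ESCs grown with A2S (day 2) completed the set. Without the cells on the authors' list of irradiated feeder MEFs, a library held 138 to 431 cells and 1727490 to 8848775 unique molecular identifiers (UMIs). The median per cell ran from 5240 UMIs in FBS day 9 A to 23194.5 in A2S day 2 B, where the letter is the replicate.

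Values in parentheses after a gene are log2 fold changes ± SE from edgeR's quasi-likelihood fit, over n = 2 libraries per group. In each comparison 13230 genes were tested. Levels are means ± SD in CPM (n = 2), scaled with TMM factors except for Eif4a1 and Acp1, which were scaled to library totals. Levels and folds sum all kept cells, so differences can lie in the share of cells, the level per cell or both. UMIs of the factors induced by doxycycline may count toward Klf4 (the sources do not say). For Pou5f1 and Sox2, 3 to 8 UMIs per group at day 4 argue against this. A fold given as "at least" was set against 3 UMIs over the group that had none. A gene with 1 to 3 UMIs in a group is given as a ratio of its UMIs summed over each group's libraries, relative to library sizes. This ratio can differ from that of the mean levels. Its 95% interval is for counting alone and leaves out the spread between libraries. Such folds and ratios are for counts without listed cells. Where leaving out a library left a group with 3 UMIs or fewer, that number is given in place of a fold. For a gene list, the members called higher and lower are given out of those tested, and the remaining members did not pass. Counts adjusted over the list alone were the same unless given. Within mm10, the pluripotency genes Pou5f1 (chromosome 17, 35506018 to 35510772) and Nanog (chromosome 6, 122707489 to 122714633), the epithelial genes Epcam (chromosome 17, 87635979 to 87651129) and Cdh1 (chromosome 8, 106603351 to 106670246), and the fibroblast genes Thy1 (chromosome 9, 44043384 to 44048579) and Col1a1 (chromosome 11, 94936224 to 94953042) are protein-coding.

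ESCs and MEFs, the end points of reprogramming, were compared first. Nanog, a core pluripotency factor, was at 377 ± 22.5 CPM in ESCs and 0.537 ± 0.524 in MEFs, and Epcam, an epithelial adhesion molecule, at 343 ± 28.8 and 0.231 ± 0.143. Other pluripotency genes were higher in ESCs, including L1td1 (at least 2861-fold higher), Dppa5a (at least 2658-fold higher), Utf1 (at least 1956-fold higher) and Sall4 (at least 1623-fold higher). Pou5f1 (at least 401-fold higher), Sox2 (10.26 ± 0.38) and Zfp42 (at least 952-fold higher) were higher as well. Further ones were Tdh (at least 1790-fold higher), Tdgf1 (ratio 19260, 3456 to 760900) and Klf4 (1.39 ± 0.14). The adhesion genes Cdh1 (ratio 2998, 1025 to 14540) and Cldn6 (at least 523-fold higher) were higher too. Matrix genes were lower in ESCs, with Tnc (at least 2433-fold lower), Col12a1 (at least 1012-fold lower), Col6a3 (at least 738-fold lower) and Postn (at least 581-fold lower). So were the smooth muscle actin gene Actg2 (at least 575-fold lower), the fibroblast markers Thy1 (-8.20 ± 0.27), Col1a1 (-10.26 ± 0.47) and Twist1 (-4.26 ± 0.27) and the cell cycle inhibitor Cdkn1a (-3.65 ± 0.12).

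Pluripotency genes had 39 of 40 higher and 0 lower (camera adjusted p = 9.35e-19). Epithelial genes had 22 of 26 higher and 1 lower (camera adjusted p = 1.84e-08). The lower epithelial member was Krt19 (-1.26 ± 0.34). Fibroblast matrix genes had 0 of 30 higher and 30 lower (camera adjusted p = 9.20e-18). Mesenchymal regulators such as Runx2 (at least 158-fold lower) and Prrx1 (ratio 5.17e-04, 1.07e-04 to 0.00151) had 0 of 24 higher and 24 lower (camera adjusted p = 3.98e-14). S phase genes, with Hells (3.20 ± 0.16), had 39 of 42 higher and 1 lower (camera adjusted p = 3.42e-10, adjusted p = 0.112 with an estimated correlation). Germline genes, among them Dmrt1 (at least 174-fold higher), had 21 of 28 higher and 1 lower (camera adjusted p = 3.35e-07). The fit called 9503 genes (4803 higher, 4700 lower). Genes named without a p had adjusted p of 0.00142 or less.

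The early response to doxycycline in serum was read from FBS day 3 against MEFs. Matrix genes fell, among them Postn (-6.75 ± 0.49), Lrrc15 (-6.55 ± 0.47) and Crispld2 (-5.99 ± 0.52), and the smooth muscle calponin Cnn1 (-5.76 ± 0.26). Foxs1 (-5.55 ± 0.40) and Igfbp2 (-4.75 ± 0.62, log2 -1.02 and adjusted p = 0.108 with listed cells kept) fell too. Col1a1 went to 269.8 ± 53.1 CPM from 1721 ± 190.5 in MEFs (-2.67 ± 0.24), Thy1 to 285 ± 34.0 from 1159 ± 58.0 (-2.02 ± 0.16). Genes that rose included Laptm5 (at least 269-fold higher), a lysosomal membrane protein of blood cells, Cd34 (7.42 ± 0.17) and Tek (6.07 ± 0.33), and the enzyme genes Urah (ratio 498, 169.8 to 2422) and Aldh3a1 (ratio 285, 96.9 to 1388). Cdh1 (ratio 22.6, 7.09 to 115) was higher, at 4.94 ± 0.0946 CPM. Klf4 (-0.03 ± 0.15, adjusted p = 0.926), Twist1 (-0.33 ± 0.17, adjusted p = 0.119, 0.0194 with no count filter, 0.0231 in a fit of the compared groups alone) and Cdkn1a (-0.20 ± 0.10, adjusted p = 0.0993, 0.0403 with RLE factors, 0.0341 with no count filter, 0.0435 with DESeq2, log2 -0.33 and adjusted p = 0.0415 without FBS day 3 A) gave no call.

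Interferon-response genes, which encode antiviral proteins, had 28 of 31 higher and 0 lower (camera adjusted p = 9.35e-11, adjusted p = 0.315 with an estimated correlation), with Ifi44 (6.14 ± 0.66) and Oas1a (5.99 ± 0.70). Cells on the feeder list were 35.8% and 26.9% of barcodes in the FBS day 3 libraries and 3.25% and 2.93% in MEFs. Matrix genes had 1 of 30 higher and 27 lower (camera adjusted p = 2.72e-13), with Fbln5 (1.01 ± 0.11) the higher member. Mesenchymal regulators, Snai1 (-2.64 ± 0.24, -1.49 with listed cells kept) and Runx1 (-2.24 ± 0.16) among them, had 1 of 24 higher and 17 lower (camera adjusted p = 1.54e-05). G2/M genes such as Hmgb2 (1.85 ± 0.15) and Cdc20 (1.70 ± 0.14) had 41 of 52 higher and 0 lower (42 and 0 adjusted over the list alone, camera adjusted p = 2.73e-12, adjusted p = 0.238 with an estimated correlation, higher count 27 without MEF A). p53 and senescence genes such as Cdkn2a (2.01 ± 0.22) and Gdf15 (1.96 ± 0.24) had 12 of 26 higher and 4 lower (camera adjusted p = 0.00443, adjusted p = 0.315 with an estimated correlation). Pluripotency genes had 7 of 40 higher and 3 lower (camera adjusted p = 0.0965, camera adjusted p = 0.0246 without FBS day 3 A). In total 5393 genes (2624 higher, 2769 lower) changed, with adjusted p of 1.44e-06 or less where a called gene has none beside it.

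From day 3 to day 12 in serum, Nanog rose to 67.7 ± 23.1 CPM (6.75 ± 0.46), Epcam to 52.2 ± 19.2 CPM (ratio 344, 60.9 to 13640) and Tdh, threonine dehydrogenase, to 189.9 ± 48.2 CPM (ratio 428, 146 to 2080). Trh (at least 466-fold higher), Tdgf1 (at least 149.5-fold higher) and Sall4 (at least 81.3-fold higher) rose. So did Esrrb (at least 63.3-fold higher) and Dppa5a (at least 51.8-fold higher), the epithelial factor Ehf (at least 178-fold higher) and the neuropeptide gene Tac2 (ratio 808, 144 to 31990). Antiviral genes fell, including Usp18 (-6.94 ± 0.93), Oasl2 (-6.50 ± 0.95), Isg15 (-6.46 ± 1.04) and Irf7 (-5.39 ± 0.86). Fibroblast genes were higher at day 12, with Thy1 (1.09 ± 0.16), Col1a1 (1.22 ± 0.24), Postn (4.80 ± 0.57, 2.83 with listed cells kept) and Eln (4.67 ± 0.44). Twist1 (0.61 ± 0.18, adjusted p = 0.0796 without FBS day 3 A, 0.118 without FBS day 12 A, log2 0.39 and adjusted p = 0.0676 with listed cells kept) rose. Klf4 (-0.37 ± 0.17, adjusted p = 0.0801) and Cdkn1a (-0.04 ± 0.10, adjusted p = 0.772) gave no call.

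Pluripotency genes had 37 of 40 higher and 1 lower (37 and 2 adjusted over the list alone, camera adjusted p = 1.29e-21). Epithelial genes had 19 of 26 higher and 2 lower (camera adjusted p = 7.03e-07, adjusted p = 0.0683 with an estimated correlation). The keratins Krt18 (-4.03 ± 0.92) and Krt19 (-2.86 ± 0.25) were lower. Interferon-response genes had 0 of 31 higher and 31 lower (camera adjusted p = 5.03e-10, adjusted p = 0.239 with an estimated correlation), with feeder-list barcodes at 7.50% and 6.40% at day 12 against 35.8% and 26.9% at day 3. Matrix genes had 19 of 30 higher and 2 lower (camera adjusted p = 5.08e-04, adjusted p = 0.194 with an estimated correlation). G2/M genes, Anln (-1.94 ± 0.15) among them, had 1 of 52 higher and 45 lower (1 and 46 adjusted over the list alone, camera adjusted p = 1.77e-14, adjusted p = 0.144 with an estimated correlation). Oxidative phosphorylation genes, with Cycs (-1.52 ± 0.19), had 1 of 40 higher and 19 lower (2 and 19 adjusted over the list alone, camera adjusted p = 0.00233, adjusted p = 0.622 with an estimated correlation). The macrophage marker Lyz2 (3.42 ± 1.03, adjusted p = 0.0553 without FBS day 3 A, 0.0510 without FBS day 3 B, log2 0.76 and adjusted p = 0.488 with listed cells kept, -0.88 without FBS day 12 B with adjusted p = 0.751) rested on FBS day 12 B. The fit called 6044 genes (3110 higher, 2934 lower), with adjusted p of 0.00831 or less for genes named without one.

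FBS day 12 cells were set against ESCs. Genes higher in them included Fmod (at least 1216-fold higher), Prelp (at least 1096-fold higher), Col12a1 (at least 622-fold higher) and Tnc (at least 528-fold higher). Il1rn (at least 1112-fold higher), the interleukin receptor antagonist, and Serpina3n (at least 977-fold higher) were higher too. Thy1 (7.27 ± 0.28), Col1a1 (8.80 ± 0.49, 5.68 with listed cells kept), Twist1 (4.54 ± 0.28) and Cdkn1a (3.41 ± 0.13) were above ESC levels. Pluripotency genes were below them, with Nanog (-2.46 ± 0.19), Sall4 (-3.27 ± 0.18), Sox2 (-3.63 ± 0.24), Zfp42 (-4.68 ± 0.23), Esrrb (-2.86 ± 0.20) and Pou5f1 (-4.64 ± 0.37). Lower too were Klf4 (-1.79 ± 0.17) and Tdh (-1.04 ± 0.20). Epcam (-2.73 ± 0.19) and Cdh1 (-3.53 ± 0.15) were lower. Olig1 (at least 63.9-fold lower) and Gbx2 (ratio 0.00760, 9.17e-04 to 0.0277), the imprinted gene Phlda2 (-7.53 ± 0.38) and the de novo methyltransferase Dnmt3b (-4.97 ± 0.22) were lower too.

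Pluripotency genes, with Lin28a (-5.40 ± 0.25), had 1 of 40 higher and 35 lower (camera adjusted p = 7.72e-10). Matrix genes had 30 of 30 higher and 0 lower (camera adjusted p = 3.30e-17). Mesenchymal regulators had 24 of 24 higher and 0 lower (camera adjusted p = 3.60e-13). Among S phase genes, Hells (-3.46 ± 0.19) included, there were 1 of 42 higher and 40 lower (1 and 41 adjusted over the list alone, camera adjusted p = 1.44e-13, adjusted p = 0.0804 with an estimated correlation). Among G2/M genes there were 0 of 52 higher and 50 lower (2 and 50 adjusted over the list alone, camera adjusted p = 3.68e-13, adjusted p = 0.114 with an estimated correlation). p53 and senescence genes, with Fas (ratio 208, 57.1 to 1727) and Cdkn2b (4.29 ± 0.32), had 16 of 26 higher and 3 lower (camera adjusted p = 0.00298, adjusted p = 0.172 with an estimated correlation). Germline genes had 0 of 28 higher and 19 lower (camera adjusted p = 3.87e-07). Calls covered 8776 genes (4547 higher, 4229 lower), with adjusted p of 3.65e-05 or less for each gene named.

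The first days with A2S were read from A2S day 2 against MEFs. The immediate-early factors Egr1 (-7.41 ± 0.31, 0 UMIs left without A2S day 2 A) and Egr2 (at least 133-fold lower) fell, and so did Spry1 (-3.58 ± 0.28), a feedback inhibitor of ERK signalling. Matrix genes fell, among them Eln (ratio 0.00319, 8.06e-05 to 0.0179), Postn (-6.29 ± 0.45, -3.70 with listed cells kept), Col5a3 (-6.78 ± 0.25, -4.10 with listed cells kept) and Crispld2 (at least 314-fold lower). Col1a1 went to 259 ± 10.4 CPM (-2.73 ± 0.24, -0.88 with listed cells kept) and Thy1 to 156 ± 0.898 CPM (-2.89 ± 0.17), while Klf4 (-1.29 ± 0.16) was lower. Sprr2b (ratio 2689, 482 to 106300), a cornified envelope gene, rose, with Elmod1 (ratio 646, 178 to 5347), Qrfpr (ratio 705, 126 to 27920), Urah (ratio 505, 172 to 2455) and Aldh3a1 (ratio 251, 85.3 to 1221). Cdh1 (ratio 30.1, 9.75 to 150.5) was higher, and Epcam (ratio 4.54, 1.09 to 26.6, adjusted p = 0.117), Twist1 (-0.37 ± 0.17, adjusted p = 0.0671, 0.0214 with RLE factors, 0.00729 with no count filter, 0.0448 with DESeq2, 0.00452 in a fit of the compared groups alone, 0.0375 without A2S day 2 B) and Cdkn1a (-0.07 ± 0.10, adjusted p = 0.586) gave no call.

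ERK target genes had 1 of 19 higher and 13 lower (camera adjusted p = 5.53e-05). Wnt targets had 3 of 18 higher and 3 lower (camera adjusted p = 0.752), with Axin2 (2.92 ± 0.31) and Tcf7 (2.17 ± 0.55, adjusted p = 0.0768 without A2S day 2 B) higher. Matrix genes had 0 of 30 higher and 29 lower (camera adjusted p = 1.56e-19). Mesenchymal regulators, with Pdgfra (-4.07 ± 0.27) and Pdgfrb (-3.79 ± 0.21, -2.28 with listed cells kept), had 1 of 24 higher and 21 lower (1 and 22 adjusted over the list alone, camera adjusted p = 1.57e-09). Interferon-response genes such as Ifi44 (5.85 ± 0.66) and Irf7 (5.71 ± 0.65) had 29 of 31 higher and 0 lower (camera adjusted p = 1.82e-08, adjusted p = 0.372 with an estimated correlation). Feeder-list barcodes were 27.2% and 22.8% of the A2S day 2 libraries. Macrophage and blood genes had 7 of 12 higher and 0 lower (camera adjusted p = 0.0484, adjusted p = 0.607 with an estimated correlation, camera adjusted p = 0.0667 without A2S day 2 B, higher count 2 without A2S day 2 B, 4 without MEF A, 3 without MEF B). S phase genes had 32 of 42 higher and 0 lower (camera adjusted p = 1.74e-08, adjusted p = 0.223 with an estimated correlation). Imprinted genes, with H19 (-6.42 ± 0.65) and Igf2 (-5.10 ± 0.46), had 3 of 22 higher and 13 lower (4 and 13 adjusted over the list alone, camera adjusted p = 0.00257). Epithelial genes, Cldn4 (at least 7.95-fold higher) and Dsp (4.68 ± 0.47) among them, had 9 of 26 higher and 1 lower (camera adjusted p = 0.0308, adjusted p = 0.372 with an estimated correlation). In all, 6592 genes (3393 higher, 3199 lower) changed, with adjusted p of 0.00208 or less for called genes without one. The A2S libraries stood apart from all others in a few genes: Eif4a1 was at 24.3 ± 2.53 CPM in A2S day 2 and 252 ± 8.54 in MEF.

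From day 2 to day 6 with A2S, Nanog went from 0.499 ± 0.0565 to 259 ± 39.0 CPM (8.92 ± 0.36), Epcam from 1.02 ± 0.466 to 324 ± 40.3 (8.30 ± 0.31) and Cdh1 from 6.44 ± 2.25 to 268 ± 18.7 (5.35 ± 0.19). Pluripotency genes that rose included Tdgf1 (at least 506-fold higher), Dppa5a (at least 198-fold higher), Dppa3 (ratio 515, 91.9 to 20390), Sall4 (ratio 192, 65.3 to 934), Esrrb (ratio 399.6, 71.2 to 15830), Tdh (8.07 ± 0.40, 0 UMIs left without A2S day 2 B) and Pou5f1 (ratio 68.1, 22.9 to 334). The epithelial genes Elf3 (at least 184-fold higher), Cldn6 (at least 159-fold higher) and Cldn7 (at least 47.4-fold higher) rose with them. Antiviral genes fell, with Isg15 (ratio 0.00125, 3.16e-05 to 0.00698), Usp18 (ratio 0.00187, 2.27e-04 to 0.00678), Rtp4 (-7.43 ± 0.90) and Ifi44 (-7.33 ± 0.93). Thy1 (-1.13 ± 0.18) and Col1a1 (-1.29 ± 0.26, -2.58 with listed cells kept) fell below their day 2 levels, and Klf4 (-0.36 ± 0.20, adjusted p = 0.133, 0.0474 with listed cells kept, log2 -0.63 and adjusted p = 0.0417 without A2S day 6 A), Twist1 (-0.30 ± 0.18, adjusted p = 0.172) and Cdkn1a (-0.03 ± 0.10, adjusted p = 0.809) gave no call.

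Pluripotency genes had 37 of 40 higher and 0 lower (camera adjusted p = 3.33e-22). Epithelial genes had 24 of 26 higher and 1 lower (camera adjusted p = 1.04e-13). Glycolysis genes, Aldoc (5.24 ± 0.45) and Slc16a3 (4.83 ± 0.36) among them, had 20 of 23 higher and 0 lower (camera adjusted p = 2.17e-09). Interferon-response genes had 0 of 31 higher and 31 lower (camera adjusted p = 1.33e-10, adjusted p = 0.193 with an estimated correlation), with feeder-list barcodes at 1.29% and 0.386% at day 6 against 27.2% and 22.8% at day 2. Mesenchymal regulators, with Twist2 (at least 31.0-fold lower) and Osr1 (ratio 0.0388, 0.00787 to 0.117), had 0 of 24 higher and 19 lower (0 and 20 adjusted over the list alone, camera adjusted p = 3.94e-09). Contractile genes, with Cnn1 (ratio 0.0145, 0.00174 to 0.0532) and Myl9 (-5.74 ± 0.37), had 0 of 20 higher and 19 lower (camera adjusted p = 3.71e-11). Amino acid and unfolded-protein stress genes, with Chac1 (-2.89 ± 0.46) and Mthfd2 (-2.22 ± 0.14), had 2 of 25 higher and 17 lower (3 and 19 adjusted over the list alone, camera adjusted p = 1.92e-04, adjusted p = 0.115 with an estimated correlation). Germline genes, Tex19.1 (at least 31.7-fold higher) among them, had 11 of 28 higher and 0 lower (camera adjusted p = 9.58e-04, higher count 7 without A2S day 2 A, 7 without A2S day 2 B). Altogether 6682 genes (3224 higher, 3458 lower) changed, and called genes without a p had adjusted p of 9.92e-05 or less.

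A2S and FBS media were compared at day 6. A2S cells were higher in pluripotency genes, with Tdgf1 (at least 368-fold higher), Dppa5a (at least 144-fold higher), Dppa3 (at least 125-fold higher), Nanog (ratio 1516, 272 to 59900), Esrrb (at least 96.7-fold higher) and Sall4 (6.63 ± 0.39, 0 UMIs left without FBS day 6 A). They were higher in the epithelial genes Cldn4 (at least 121-fold higher), Epcam (8.04 ± 0.32), Cdh1 (4.26 ± 0.18) and Krt18 (at least 61.1-fold higher). Genes lower with A2S included Ogn (-6.85 ± 0.47, -4.48 with listed cells kept), Tnc (-5.99 ± 0.24), Fgf7 (ratio 0.00473, 5.71e-04 to 0.0172), Eln (at least 67.7-fold lower) and Postn (-4.96 ± 0.71). Lower too were Egr1 (-8.64 ± 0.43) and the defensin Defb1 (ratio 0.00349, 4.21e-04 to 0.0127). Thy1 (-2.76 ± 0.18), Col1a1 (-2.48 ± 0.26), Twist1 (-0.83 ± 0.18), Klf4 (-1.54 ± 0.19) and Cdkn1a (-0.40 ± 0.10) were lower too.

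Pluripotency genes had 34 of 40 higher and 2 lower (35 and 2 adjusted over the list alone, camera adjusted p = 1.12e-17). Epithelial genes had 24 of 26 higher and 2 lower (camera adjusted p = 3.54e-12). Matrix genes had 0 of 30 higher and 30 lower (camera adjusted p = 1.12e-17). ERK targets, with Dusp6 (-3.41 ± 0.25), had 2 of 19 higher and 15 lower (camera adjusted p = 5.85e-05). G2/M genes had 45 of 52 higher and 0 lower (46 and 0 adjusted over the list alone, camera adjusted p = 3.09e-12, adjusted p = 0.0953 with an estimated correlation). Glycolysis genes such as Slc16a3 (3.93 ± 0.34) and Slc2a3 (2.90 ± 0.15) had 19 of 23 higher and 2 lower (camera adjusted p = 5.37e-06). Imprinted genes had 3 of 22 higher and 14 lower (camera adjusted p = 0.00655), where Phlda2 (at least 36.8-fold higher) and Peg10 (4.05 ± 0.29) were higher and Dlk1 (-4.13 ± 0.36) and Cdkn1c (-3.50 ± 0.33) lower. Calls were made for 6970 genes (3498 higher, 3472 lower), with adjusted p of 0.00101 or less for each gene named. Eif4a1 was at 24.9 ± 0.930 CPM in A2S day 6 and 345 ± 30.2 in FBS day 6, the split that set A2S libraries apart.

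A2S day 6 cells were set against ESCs grown with the same molecules. Nanog was at 259 ± 39.0 CPM against 1236 ± 5.93 (-2.25 ± 0.16), and Sall4 (-2.46 ± 0.15), Sox2 (-3.64 ± 0.23), Zfp42 (-4.94 ± 0.18) and Esrrb (-2.90 ± 0.17) were lower as well. Pou5f1 (-1.33 ± 0.25), Cdh1 (-1.32 ± 0.12), Tdh (-2.35 ± 0.19) and Klf4 (-3.35 ± 0.17) were also lower, but Epcam was higher, at 324 ± 40.3 CPM against 125 ± 5.50 (1.38 ± 0.16). Nanog was at 914.6 CPM in cluster 9 (fraction 0.82 A2S day 6), 159.8 in cluster 7 (0.28) and 1205 in cluster 10 (ESC with A2S), untested. Reprogramming cells were higher in Prelp (at least 249-fold higher), Acsbg1 (at least 214-fold higher), Mgst1 (9.44 ± 0.29, 5.03 with listed cells kept) and Avil (ratio 389, 133 to 1889), in the fibroblast genes Thy1 (3.08 ± 0.27, 1.49 with listed cells kept), Twist1 (4.91 ± 0.32, 1.86 with listed cells kept) and Col1a1 (2.17 ± 0.32, -1.73 with listed cells kept with adjusted p = 1.46e-06) and in Cdkn1a (1.64 ± 0.10, 0.62 with listed cells kept). They were lower in Dazl (ratio 8.07e-04, 1.66e-04 to 0.00236), Pramel6 (at least 236-fold lower) and Magea8 (at least 120.4-fold lower, adjusted p = 0.310 with DESeq2). Lower too were the glutamate transporter gene Slc1a1 (ratio 0.00151, 3.83e-05 to 0.00845) and the Y-linked Eif2s3y (at least 263-fold lower).

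Germline genes had 0 of 28 higher and 27 lower (camera adjusted p = 1.72e-18). Pluripotency genes, with Dnmt3l (-6.59 ± 0.30) and Dppa2 (-5.23 ± 0.25), had 1 of 40 higher and 36 lower (camera adjusted p = 1.09e-10). Imprinted genes, with H19 (ratio 1381, 248 to 54610), had 17 of 22 higher and 1 lower (camera adjusted p = 8.85e-05). Glycolysis genes, Eno2 (4.17 ± 0.44) among them, had 18 of 23 higher and 3 lower (camera adjusted p = 3.09e-05). Epithelial genes, with Perp (4.69 ± 0.16) and Esrp1 (3.88 ± 0.43), had 18 of 26 higher and 6 lower (camera adjusted p = 0.0327, adjusted p = 0.348 with an estimated correlation). Mesenchymal regulators such as Prrx1 (5.46 ± 0.26, log2 0.03 and adjusted p = 0.926 with listed cells kept) and Cd44 (5.41 ± 0.22, 0.71 with listed cells kept) had 18 of 24 higher and 1 lower (camera adjusted p = 7.70e-06). Matrix genes had 21 of 30 higher and 1 lower (21 and 3 adjusted over the list alone, camera adjusted p = 2.49e-05, adjusted p = 0.168 with an estimated correlation). Feeder-list barcodes were 14.2% and 10.9% of the ESC with A2S libraries. S phase genes had 2 of 42 higher and 32 lower (camera adjusted p = 1.19e-05, adjusted p = 0.296 with an estimated correlation). This comparison called 8385 genes (4210 higher, 4175 lower), with adjusted p of 3.33e-05 or less for genes without one.

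Without the DOT1L inhibitor (A2 against A2S), Epcam at day 4 was at 5.93 ± 2.54 CPM against 58.3 ± 17.3 (-3.46 ± 0.29) and Cdh1 at 45.8 ± 3.46 against 161 ± 16.7 (-1.81 ± 0.15). Nanog (-3.27 ± 0.45), Sall4 (ratio 0.0212, 0.00431 to 0.0635) and Tdh (-1.36 ± 0.27, adjusted p = 0.0566 without A2 day 4 A) were lower. Lower too were Tgm3 (-2.88 ± 0.55) and Apoe (-2.96 ± 0.30). The imprinted RNA H19 (5.71 ± 1.10), the matrix genes Mgp (3.98 ± 0.47) and Tnc (2.79 ± 0.26) and the contractile genes Tagln (2.55 ± 0.27) and Acta2 (1.94 ± 0.24) were higher. Klf4 (0.91 ± 0.25, adjusted p = 0.125 without A2S day 4 A, 0.179 without A2 day 4 A) and Cdkn1a (0.41 ± 0.10, adjusted p = 0.0663 without A2S day 4 B, 0.145 without A2 day 4 A) were higher. Thy1 (0.12 ± 0.18, adjusted p = 0.767), Col1a1 (0.80 ± 0.28, adjusted p = 0.0555, 0.00188 with no count filter, 2.13e-04 in a fit of the compared groups alone, 0.0371 without A2S day 4 B, log2 1.32 and adjusted p = 0.00140 with listed cells kept) and Twist1 (0.05 ± 0.19, adjusted p = 0.933) gave no call. Pluripotency genes had 3 of 40 higher and 21 lower (camera adjusted p = 9.33e-09, lower count 13 without A2S day 4 A, 12 without A2 day 4 A). Epithelial genes had 2 of 26 higher and 14 lower (2 and 15 adjusted over the list alone, camera adjusted p = 1.52e-06, lower count 8 without A2 day 4 A). Wnt targets, with Sp5 (at least 9.59-fold lower, adjusted p = 0.0837 without A2 day 4 A), had 1 of 18 higher and 7 lower (1 and 10 adjusted over the list alone, camera adjusted p = 2.62e-05, lower count 4 without A2S day 4 A, 2 without A2 day 4 A). Matrix genes had 14 of 30 higher and 0 lower (18 and 0 adjusted over the list alone, camera adjusted p = 2.20e-08, higher count 9 without A2S day 4 A). Contractile genes had 14 of 20 higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 4.69e-10). Feeder-list barcodes were 1.62% and 1.14% in A2 and 0.417% and 0% in A2S. Changes covered 1899 genes (1033 higher, 866 lower), with adjusted p of 0.0103 or less where none is given. The count was 939 without A2S day 4 A, 1205 without A2S day 4 B and 856 without A2 day 4 A.

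At day 6 without the inhibitor, Nanog was at 12.4 ± 0.895 CPM against 259 ± 39.0 (-4.38 ± 0.22) and Epcam at 13.4 ± 5.11 against 324 ± 40.3 (-4.62 ± 0.21). Other pluripotency genes were lower, with Dppa5a (at least 166-fold lower), Dppa3 (at least 143-fold lower), Tdgf1 (-7.67 ± 0.36), Pou5f1 (-5.33 ± 0.51), Sall4 (-3.00 ± 0.23), Sox2 (-2.56 ± 0.35) and Tdh (-1.98 ± 0.21), as was Cdh1 (-1.44 ± 0.13). Higher genes included Ogn (5.41 ± 0.52, 3.03 with listed cells kept), Tnc (3.82 ± 0.28), Acta2 (3.34 ± 0.28) and Eln (at least 27.1-fold higher). So were Il1rn (4.59 ± 0.40), Thy1 (0.92 ± 0.18, 0.58 without A2S day 6 B), Col1a1 (1.77 ± 0.26), Twist1 (0.71 ± 0.18) and Cdkn1a (0.79 ± 0.10). Klf4 (0.02 ± 0.21, adjusted p = 0.981) gave no call. Pluripotency genes had 0 of 40 higher and 36 lower (camera adjusted p = 1.55e-31). Epithelial genes, with Cldn7 (at least 39.5-fold lower) and Rab25 (at least 22.2-fold lower), had 1 of 26 higher and 23 lower (1 and 24 adjusted over the list alone, camera adjusted p = 8.90e-16). Glycolysis genes, with Slc16a3 (-2.69 ± 0.29) and Slc2a3 (-2.50 ± 0.15), had 2 of 23 higher and 16 lower (2 and 17 adjusted over the list alone, camera adjusted p = 7.02e-08). Matrix genes had 24 of 30 higher and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 1.26e-11). p53 and senescence genes had 11 of 26 higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 5.67e-04, adjusted p = 0.140 with an estimated correlation). Feeder-list barcodes were 4.26% and 0.755% in A2 and 1.29% and 0.386% in A2S. S phase genes had 0 of 42 higher and 20 lower (1 and 23 adjusted over the list alone, camera adjusted p = 1.86e-06, adjusted p = 0.210 with an estimated correlation). At this day 4075 genes (2210 higher, 1865 lower) changed, with adjusted p of 0.00299 or less for called genes. The count was 2708 without A2S day 6 B and 2701 without A2 day 6 B.

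Without ascorbic acid (S2 against A2S), lower genes at day 4 included Adh7 (-3.58 ± 0.30), Peg10 (-2.65 ± 0.26), Adamts5 (-2.16 ± 0.31, -1.41 with listed cells kept) and Mdk (-2.06 ± 0.20). Nanog (-1.18 ± 0.35, adjusted p = 0.129 without A2S day 4 A, 0.136 without A2S day 4 B, 0.153 without S2 day 4 A, 0.146 without S2 day 4 B), Sall4 (-2.0 ± 0.33), Epcam (-1.39 ± 0.23, adjusted p = 0.0604 without A2S day 4 A) and Thy1 (-1.95 ± 0.22, log2 -0.66 and adjusted p = 0.183 with listed cells kept) were lower in the panel. Alpl (1.73 ± 0.23), tissue-nonspecific alkaline phosphatase, Dusp1 (1.67 ± 0.19), a MAP kinase phosphatase, and Pcx (1.64 ± 0.20), pyruvate carboxylase, were higher, as was Klf4 (1.09 ± 0.25, adjusted p = 0.115 without A2S day 4 A, 0.119 without S2 day 4 B). Cdh1 (-0.30 ± 0.14, adjusted p = 0.227), Tdh (-0.29 ± 0.25, adjusted p = 0.579), Col1a1 (0.59 ± 0.29, adjusted p = 0.262, log2 2.15 and adjusted p = 5.94e-06 with listed cells kept, log2 1.17 and adjusted p = 0.00605 without S2 day 4 A), Twist1 (-0.18 ± 0.19, adjusted p = 0.668) and Cdkn1a (0.19 ± 0.10, adjusted p = 0.292) gave no call. Pluripotency genes, with Tdgf1 (-3.21 ± 0.57) and Zscan10 (-2.67 ± 0.39), had 1 of 40 higher and 13 lower (1 and 14 adjusted over the list alone, camera adjusted p = 2.74e-05, adjusted p = 0.0782 with an estimated correlation, lower count 8 without A2S day 4 A, 8 without S2 day 4 B). Contractile genes, with Cald1 (0.97 ± 0.13), had 4 of 20 higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.27e-04, adjusted p = 0.334 with an estimated correlation, camera adjusted p = 0.142 without S2 day 4 B, higher count 2 without A2S day 4 B, 2 without S2 day 4 B). Matrix genes, with Fbln5 (1.33 ± 0.14), had 10 of 30 higher and 3 lower (14 and 3 adjusted over the list alone, camera adjusted p = 0.00305, adjusted p = 0.556 with an estimated correlation, camera adjusted p = 0.455 without S2 day 4 B, higher count 3 without A2S day 4 A, 5 without A2S day 4 B, 3 without S2 day 4 B). Feeder-list barcodes were 9.86% and 13.8% in S2 day 4 and 0.417% and 0% in A2S day 4. Epithelial genes had 1 of 26 higher and 4 lower (camera adjusted p = 0.407, lower count 0 without A2S day 4 A, 2 without S2 day 4 A, 2 without S2 day 4 B). Here 867 genes (448 higher, 419 lower) changed, with adjusted p of 0.0352 or less for called genes without one. The count was 285 without A2S day 4 A, 488 without A2S day 4 B, 481 without S2 day 4 A and 532 without S2 day 4 B.

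At day 6 without ascorbic acid, pluripotency genes were lower, with Dppa5a (at least 139.6-fold lower), Dppa3 (-6.43 ± 0.46), Tdgf1 (-4.77 ± 0.27), Pou5f1 (ratio 0.0209, 0.00426 to 0.0621), Sox2 (-5.28 ± 0.54), Zfp42 (-3.59 ± 0.45) and Esrrb (-4.78 ± 0.35). Nanog was at 58.9 ± 1.04 CPM against 259 ± 39.0 (-2.14 ± 0.18). Sall4 (-1.71 ± 0.20), Epcam (-1.06 ± 0.16) and Tdh (-1.10 ± 0.20) were lower. So was Klf4 (-0.69 ± 0.24, adjusted p = 0.0634 with listed cells kept, 0.0701 in a fit of the compared groups alone, log2 -0.38 and adjusted p = 0.454 without A2S day 6 A, log2 -0.31 and adjusted p = 0.546 without S2 day 6 A, log2 -1.15 without S2 day 6 B). Cdh1 gave no call, at 243 ± 39.2 against 268 ± 18.7 CPM (-0.14 ± 0.13, adjusted p = 0.503). The contractile genes Acta2 (2.86 ± 0.28) and Tagln (2.50 ± 0.33), the neural genes Pak3 (2.18 ± 0.21) and Sox11 (1.90 ± 0.16) and Cdkn1a (0.79 ± 0.10) were higher. Thy1 (-0.51 ± 0.21, adjusted p = 0.0872, 0.0282 with no count filter, log2 -0.86 and adjusted p = 0.00938 without A2S day 6 B), Col1a1 (0.73 ± 0.26, adjusted p = 0.0551, 0.00296 with no count filter, 0.0123 in a fit of the compared groups alone, 0.0146 without S2 day 6 B, log2 1.34 and adjusted p = 4.72e-04 with listed cells kept) and Twist1 (-0.21 ± 0.19, adjusted p = 0.510) gave no call. Pluripotency genes, with Dppa4 (at least 17.3-fold lower), had 0 of 40 higher and 33 lower (0 and 35 adjusted over the list alone, camera adjusted p = 1.42e-32). Germline genes, with Rhox6 (at least 13.7-fold lower, adjusted p = 0.682 with DESeq2) and Rhox9 (at least 8.93-fold lower, adjusted p = 0.719 with DESeq2), had 0 of 28 higher and 7 lower (camera adjusted p = 2.00e-05, lower count 4 without S2 day 6 A). Epithelial genes had 2 of 26 higher and 9 lower (2 and 10 adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.387 with an estimated correlation). Contractile genes had 8 of 20 higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.00463, adjusted p = 0.335 with an estimated correlation). Feeder-list barcodes were 2.07% and 6.31% in S2 and 1.29% and 0.386% in A2S. S phase genes had 0 of 42 higher and 12 lower (1 and 19 adjusted over the list alone, camera adjusted p = 2.80e-04, adjusted p = 0.392 with an estimated correlation, lower count 4 without A2S day 6 B, 6 without S2 day 6 A). Changes reached 2126 genes (1104 higher, 1022 lower), with adjusted p of 0.0433 or less for called genes without one. The count was 1353 without A2S day 6 A, 1231 without A2S day 6 B, 1060 without S2 day 6 A and 1313 without S2 day 6 B.

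Without 2i (AS against A2S), Cdh1 at day 4 was at 14.5 ± 1.84 CPM against 161 ± 16.7 (-3.44 ± 0.18). Epcam (-3.23 ± 0.29), Nanog (-3.70 ± 0.48), Sall4 (-5.01 ± 0.50) and Tdh (-3.18 ± 0.35, -2.05 without AS day 4 B) were lower. So was Tgm3 (-4.26 ± 0.66). The keratins Krt8 (3.52 ± 0.57) and Krt18 (3.59 ± 0.59) were higher. Egr1 (5.37 ± 0.39), Fosl1 (1.98 ± 0.29), Fgf7 (ratio 132, 44.9 to 643), Bgn (3.48 ± 0.30), Thy1 (1.62 ± 0.17) and Col1a1 (1.90 ± 0.27) were higher too. Klf4 (0.57 ± 0.26, adjusted p = 0.0932), Twist1 (0.20 ± 0.19, adjusted p = 0.469, log2 0.60 and adjusted p = 0.0177 without AS day 4 B) and Cdkn1a (-0.22 ± 0.10, adjusted p = 0.103) gave no call. Epithelial genes had 4 of 26 higher and 15 lower (camera adjusted p = 0.00142, adjusted p = 0.204 with an estimated correlation), pluripotency genes 2 of 40 higher and 21 lower (camera adjusted p = 6.40e-08). Matrix genes had 24 of 30 higher and 0 lower (camera adjusted p = 1.10e-15), with feeder-list barcodes at 6.08% and 9.23% in AS day 4 and 0.417% and 0% in A2S day 4. ERK targets had 8 of 19 higher and 2 lower (camera adjusted p = 0.00228, adjusted p = 0.0868 with an estimated correlation, camera adjusted p = 0.0501 without AS day 4 A). Wnt targets had 1 of 18 higher and 11 lower (1 and 12 adjusted over the list alone, camera adjusted p = 6.44e-05, lower count 6 without AS day 4 B). Glycolysis genes had 2 of 23 higher and 13 lower (2 and 14 adjusted over the list alone, camera adjusted p = 2.29e-04, lower count 7 without A2S day 4 A).

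Interferon-response genes separated the pair of AS day 4 libraries. They took 0.534% of UMIs in AS day 4 B and 0.195% in AS day 4 A, against 0.149% and 0.153% in A2S day 4, and 0.471% and 0.503% in FBS day 3. Feeder-list barcodes were 6.08% and 9.23% in AS day 4 A and B. Over both libraries the list had 30 of 31 higher and 0 lower (camera adjusted p = 6.40e-08, adjusted p = 0.369 with an estimated correlation, camera adjusted p = 0.153 without AS day 4 B, higher count 4 without AS day 4 B), with Isg15 (ratio 253, 86.2 to 1227, adjusted p = 0.356 without AS day 4 B), Ifi44 (6.43 ± 0.94, log2 1.15 and adjusted p = 0.480 without AS day 4 B) and Oasl2 (6.29 ± 0.94, log2 1.07 and adjusted p = 0.526 without AS day 4 B). Isg15 was at 2.04 CPM in AS day 4 A and 194 in AS day 4 B. The macrophage marker Lyz2 (ratio 79.6, 13.9 to 3178, adjusted p = 0.229 without A2S day 4 A, 0.140 without A2S day 4 B, adjusted p = 0.911 without AS day 4 B with 0 UMIs left) split the pair too, at 0 CPM in AS day 4 A and 20.5 in AS day 4 B. Across the comparison 3974 genes (2108 higher, 1866 lower) changed, with adjusted p of 0.0459 or less for called genes without one. The count was 2487 without A2S day 4 A, 2613 without AS day 4 B and 1843 in a fit of the compared groups alone, where 1162 were higher.

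**Figure D1:**
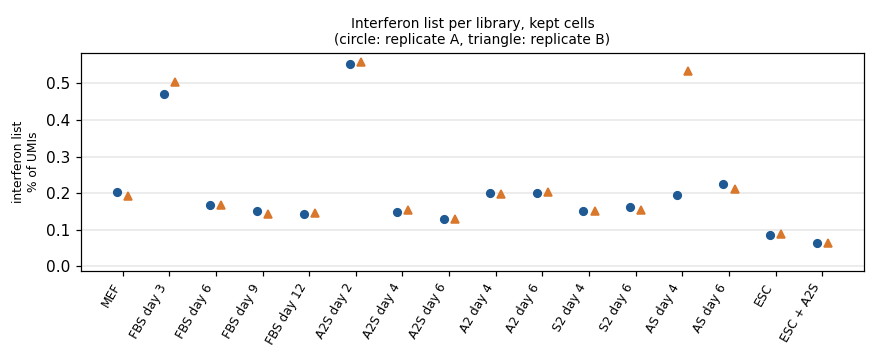
Share of UMIs in genes of the interferon-response list, in %, for each of the 32 libraries, by group. The pair of AS day 4 libraries lay apart, at 0.195% and 0.534%.

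At day 6 without 2i, the immediate-early factor Egr1 (7.63 ± 0.46) was higher. Fgf7 (ratio 162, 44.6 to 1347), Il1rn (5.31 ± 0.39), Myl9 (4.85 ± 0.40), Acta2 (4.33 ± 0.28) and Bgn (3.07 ± 0.26) were higher as well. Thy1 (2.34 ± 0.18), Col1a1 (1.96 ± 0.26) and Twist1 (0.48 ± 0.18, adjusted p = 0.0817 with listed cells kept, 0.0658 with DESeq2, 0.172 without A2S day 6 A, 0.117 without A2S day 6 B, 0.147 without AS day 6 A, 0.109 without AS day 6 B) were higher too. Nanog was at 25 ± 12.5 CPM against 259 ± 39.0 (-3.42 ± 0.20) and Epcam at 80.4 ± 9.26 against 324 ± 40.3 (-2.02 ± 0.17). Dppa5a (at least 167-fold lower), Dppa3 (-5.54 ± 0.40, 0 UMIs left without AS day 6 B) and Elf3 (-5.25 ± 0.35) were lower. So were Sall4 (-1.83 ± 0.20), Esrrb (-3.21 ± 0.27), Cdh1 (-1.77 ± 0.14) and Tdh (-2.33 ± 0.22). Klf4 (-0.73 ± 0.23, adjusted p = 0.148 without AS day 6 B, log2 -0.43 and adjusted p = 0.253 without A2S day 6 A, log2 -1.14 without AS day 6 A) was lower, and Cdkn1a (0.20 ± 0.10, adjusted p = 0.104) gave no call. ERK targets, with Etv4 (3.75 ± 0.40), had 13 of 19 higher and 1 lower (camera adjusted p = 6.96e-07). Wnt targets had 2 of 18 higher and 11 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.00155, lower count 7 without A2S day 6 A, 7 without AS day 6 A). Pluripotency genes had 2 of 40 higher and 34 lower (3 and 34 adjusted over the list alone, camera adjusted p = 6.73e-17). Epithelial genes had 3 of 26 higher and 18 lower (4 and 20 adjusted over the list alone, camera adjusted p = 3.53e-05, adjusted p = 0.0679 with an estimated correlation). Matrix genes had 25 of 30 higher and 0 lower (26 and 0 adjusted over the list alone, camera adjusted p = 2.91e-14), with feeder-list barcodes at 2.30% and 3.27% in AS and 1.29% and 0.386% in A2S. Glycolysis genes, with Pgk1 (-2.20 ± 0.19), had 2 of 23 higher and 19 lower (camera adjusted p = 7.86e-10). Oxidative phosphorylation genes had 0 of 40 higher and 27 lower (0 and 31 adjusted over the list alone, camera adjusted p = 3.26e-08, adjusted p = 0.305 with an estimated correlation, lower count 17 without A2S day 6 B). Calls numbered 5105 genes (2765 higher, 2340 lower), with adjusted p of 0.0371 or less for called genes without one.

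The 6 comparisons against A2S shared a split between libraries, since A2S was the reference in each. Eif4a1 was at 24.9 ± 0.930 CPM in A2S day 6 and 377 ± 13.1 in A2 day 6, and Acp1 at 14.8 ± 3.51 and 94.3 ± 2.87. ESCs with A2S had Eif4a1 at 995 ± 37.2 CPM. Eif4a1, a translation initiation helicase gene, lies on chromosome 11, 69666936 to 69672423, and Acp1, a phosphatase gene, on chromosome 12, 30893326 to 30911589. A2, S2 and AS lay on the same side of this split and were also compared with each other at day 6, a test added after the data were seen.

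**Figure D2:**
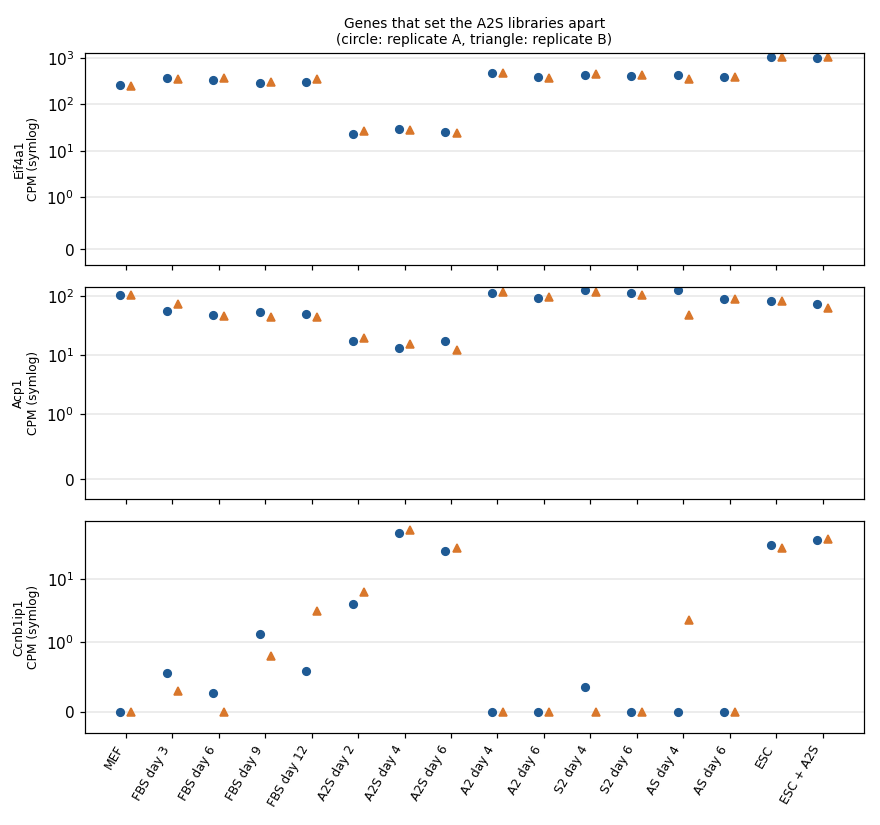
Levels of Eif4a1, Acp1 and Ccnb1ip1 in CPM of library totals for each of the 32 libraries, by group. All A2S reprogramming libraries lay below all other libraries in Eif4a1 and Acp1.

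In edgeR's fit, with every called gene of the panel given, A2 at day 6 was below S2 in Nanog (-2.24 ± 0.26), Sall4 (-1.29 ± 0.28), Epcam (-3.56 ± 0.22), Cdh1 (-1.30 ± 0.14) and Tdh (-0.87 ± 0.22). It was above S2 in Sox2 (2.73 ± 0.78), Klf4 (0.70 ± 0.23), Thy1 (1.44 ± 0.20), Col1a1 (1.04 ± 0.25) and Twist1 (0.91 ± 0.19), with adjusted p of 0.0361 or less and 2128 genes (1233 higher, 895 lower) called. AS was below S2 in Nanog (-1.28 ± 0.23), Epcam (-0.96 ± 0.17), Cdh1 (-1.64 ± 0.14), Tdh (-1.23 ± 0.23) and Cdkn1a (-0.59 ± 0.10). It was above S2 in Esrrb (1.58 ± 0.54), Thy1 (2.86 ± 0.19), Col1a1 (1.22 ± 0.25) and Twist1 (0.68 ± 0.19), with adjusted p of 0.0260 or less and 4089 genes (2285 higher, 1804 lower) called. AS was above A2 in Nanog (0.96 ± 0.29), Sall4 (1.17 ± 0.28), Epcam (2.60 ± 0.23), Esrrb (36 UMIs in AS, 1 UMI in A2) and Thy1 (1.42 ± 0.17). It was below A2 in Klf4 (-0.74 ± 0.23) and Cdkn1a (-0.59 ± 0.10), with adjusted p of 0.0190 or less and 2452 genes (1464 higher, 988 lower) changed.

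Whether the effect of each omission differed between days was tested as an interaction, in which an offset common to all A2S libraries cancels. A difference of the A2S libraries that itself changes between days does not cancel. Positive values mean a more positive effect at day 6. Without 2i, Cdh1 (1.66 ± 0.24, adjusted p = 1.55e-05) and Sall4 (3.17 ± 0.64, adjusted p = 0.00109, 0.104 without AS day 4 B) had positive values. So had Epcam (1.22 ± 0.36, adjusted p = 0.0230, 0.0535 in a fit of the compared groups alone, 0.0852 without A2S day 6 B, 0.255 without AS day 4 B, 0.0795 without AS day 6 B, log2 0.80 and adjusted p = 0.243 without A2S day 4 A). Negative values were called for Pou5f1 (-5.15 ± 1.33, adjusted p = 0.0103, 0.0862 without AS day 4 B) and Klf4 (-1.30 ± 0.34, adjusted p = 0.0119, 0.0513 in a fit of the compared groups alone, 0.0598 without A2S day 4 A, 0.0933 without A2S day 6 A, 0.0848 without AS day 4 B, 0.0573 without AS day 6 B). Without ascorbic acid, Thy1 (1.44 ± 0.31, adjusted p = 0.00820, 0.0976 without A2S day 4 A, 0.0531 without A2S day 6 B, log2 0.83 and adjusted p = 0.303 with listed cells kept) and Cdkn1a (0.60 ± 0.14, adjusted p = 0.0140, 0.0877 without A2S day 4 A, 0.0832 without A2S day 6 A, 0.102 without S2 day 4 A, 0.106 without S2 day 6 A) were positive. Klf4 (-1.78 ± 0.34, adjusted p = 0.00364) and Pou5f1 (adjusted p = 0.0333, no call with any 1 compared library other than S2 day 6 A left out, no fold given for 3 UMIs in S2 day 6) were negative. At day 4 Pou5f1 had 4 UMIs in S2 and 4 in A2S, again too few. Without the inhibitor, Sall4 (adjusted p = 0.0439, 0.0589 with listed cells kept, 0.0717 with DESeq2, no call with any 1 compared library left out, no fold given for 3 UMIs in A2 day 4) was positive. Nanog (-1.11 ± 0.67, adjusted p = 0.347), Epcam (-1.16 ± 0.44, adjusted p = 0.110, 0.0489 with no count filter, 0.0472 with DESeq2, called without A2S day 4 A or A2 day 6 A) and Cdh1 (0.37 ± 0.20, adjusted p = 0.293) gave no call. Pluripotency genes had 1 of 40 higher and 7 lower (1 and 11 adjusted over the list alone, camera adjusted p = 5.27e-21) in A2. In S2 they had 0 of 40 higher and 10 lower (1 and 14 adjusted over the list alone, camera adjusted p = 8.28e-20, lower count 3 without S2 day 4 A, 5 without S2 day 6 A). In AS they had 6 of 40 higher and 5 lower (6 and 6 adjusted over the list alone, camera adjusted p = 1.19e-04, camera down, fewer higher without A2S day 4 A or AS day 4 B). At day 4 Dppa5a had 0, Esrrb at most 1 and Zfp42 at most 4 UMIs per group, so no day 4 effect was measured for them. Glycolysis genes had 1 of 23 higher and 11 lower (1 and 14 adjusted over the list alone, camera adjusted p = 1.38e-07, lower count 7 without A2S day 4 B, 7 without A2S day 6 B, 6 without A2 day 4 A) in A2, and 1 of 23 higher and 8 lower (1 and 11 adjusted over the list alone, camera adjusted p = 7.42e-05) in AS. The test called 1047 genes (665 higher, 382 lower) for A2, 448 genes (253 higher, 195 lower) for S2 and 1440 genes (945 higher, 495 lower) for AS. The count for A2 was 549 without A2S day 4 A, 602 without A2S day 4 B, 482 without A2S day 6 B, 507 without A2 day 4 A, 618 without A2 day 6 A, 608 without A2 day 6 B and 666 with DESeq2. For S2 it was 209 without A2S day 4 A, 216 without A2S day 4 B, 243 without A2S day 6 A, 225 without A2S day 6 B, 191 without S2 day 4 A and 128 without S2 day 6 A. For AS it was 831 without A2S day 4 A, 915 without A2S day 6 B, 854 without AS day 4 B, 917 without AS day 6 A, 942 with DESeq2 and 665 in a fit of the compared groups alone.

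ESCs grown with A2S were compared with ESCs without it. Nanog rose to 1236 ± 5.93 CPM from 377 ± 22.5 (1.71 ± 0.15). Tdh (1.66 ± 0.19), Zfp42 (1.17 ± 0.14) and Esrrb (0.85 ± 0.15) were higher. Pou5f1 (-0.47 ± 0.23, adjusted p = 0.0932, 0.0198 with listed cells kept, 0.00371 in a fit of the compared groups alone, log2 -0.72 and adjusted p = 0.0466 without ESC B), Sall4 (0.14 ± 0.14, adjusted p = 0.414), Sox2 (-0.12 ± 0.19, adjusted p = 0.621), Cdh1 (0.04 ± 0.12, adjusted p = 0.843) and Klf4 (0.31 ± 0.14, adjusted p = 0.0687, 0.00213 in a fit of the compared groups alone) gave no call. The naive-state factors Tbx3 (3.90 ± 0.16) and Tfcp2l1 (3.27 ± 0.14) were higher. Crxos (at least 180.2-fold higher) and Ceacam10 (ratio 754, 135 to 29820) rose, with Pramel7 (at least 118-fold higher), Xlr3c (at least 103-fold higher) and Magea8 (at least 96.8-fold higher, adjusted p = 0.386 with DESeq2), members of multicopy families whose reads can be shared among copies, so their values are uncertain. Genes that fell included Lefty1 (-7.41 ± 0.43), a Nodal antagonist, and Sema3e (ratio 0.00462, 5.58e-04 to 0.0169), Slc16a3 (-6.39 ± 0.41), Foxp1 (-5.75 ± 0.22, -1.78 with listed cells kept) and Tagln (-5.74 ± 0.46, -2.78 with listed cells kept). Epcam (-1.46 ± 0.16) fell, and Cdkn1a (1.91 ± 0.13) and Col1a1 (4.06 ± 0.76) were higher. Twist1 (-1.31 ± 0.54, adjusted p = 0.0562 with a replicate block, 0.102 without ESC A, 0.140 without ESC B, 0.210 without ESC with A2S A, 0.0509 without ESC with A2S B, 1.42 with listed cells kept with adjusted p = 3.23e-04) was lower.

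Germline genes had 21 of 28 higher and 1 lower (22 and 2 adjusted over the list alone, camera adjusted p = 7.97e-12). Formative genes, with Pou3f1 (-4.90 ± 0.38), had 1 of 15 higher and 13 lower (2 and 13 adjusted over the list alone, camera adjusted p = 4.41e-06). Pluripotency genes, Lin28a (-3.29 ± 0.19) among them, had 18 of 40 higher and 11 lower (20 and 11 adjusted over the list alone, camera adjusted p = 0.287). Glycolysis genes, with Pdk1 (-3.84 ± 0.16), had 3 of 23 higher and 17 lower (camera adjusted p = 4.34e-05). Oxidative phosphorylation genes, with Atp5g1 (1.5 ± 0.13) and Uqcr10 (1.31 ± 0.16), had 23 of 40 higher and 1 lower (camera adjusted p = 7.73e-04, adjusted p = 0.723 with an estimated correlation). ERK targets, with Dusp4 (-3.18 ± 0.38), had 4 of 19 higher and 12 lower (4 and 14 adjusted over the list alone, camera adjusted p = 0.00245, adjusted p = 0.0781 with an estimated correlation). Epithelial genes, with Esrp1 (-5.26 ± 0.40), had 3 of 26 higher and 17 lower (camera adjusted p = 5.06e-04, adjusted p = 0.153 with an estimated correlation). Matrix genes, with Col12a1 (at least 4.69-fold higher), had 15 of 30 higher and 2 lower (camera adjusted p = 2.10e-04, adjusted p = 0.185 with an estimated correlation). Barcodes on the feeder list were 14.2% and 10.9% of the ESC with A2S libraries and 3.50% and 3.53% of the ESC libraries. The comparison called 6173 genes (3332 higher, 2841 lower), with adjusted p of 0.0443 or less for called genes without one.

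To compare shares of cells, each cell was thinned to 1000 UMIs and the cells with a UMI of a gene were counted, as mean % ± SD (n = 2 libraries). Nanog was seen in 18.9% ± 1.61 of A2S day 6 cells, against 5.04% ± 0.536 in S2, 2.00% ± 0.616 in AS and 0.793% ± 0.492 in A2 at that day. The Nanog share was 4.27% ± 0.0805 at FBS day 12, 31.2% ± 1.93 in ESCs and 65.8% ± 3.80 in ESCs with A2S, and in MEFs, which should lack Nanog, 0.116% ± 0.164. Epcam was seen in 28.0% ± 3.42 of A2S day 6 cells, 13.1% ± 1.83 in S2, 6.84% ± 1.36 in AS, 2.00% ± 0.939 in A2, and in 4.53% ± 0.292 at FBS day 12, 26.9% ± 4.22 in ESCs and 10.5% ± 0.486 in ESCs with A2S. MEFs had 0 of 298 (at most 1.01%) and 431 (at most 0.696%), where the bracket is what a count of 0 allows. The collagen gene Col1a2 was seen in 91.4% ± 2.24 of MEFs, 57.9% ± 5.24 of FBS day 12 cells, 24.4% ± 1.71 of A2S day 6 cells and 0 of 138 (at most 2.17%) and 164 (at most 1.83%) ESCs. Without thinning, A2S day 6 shares were 48.8% ± 0.10 for Nanog, 73.8% ± 6.28 for Epcam and 49.4% ± 1.40 for Col1a2, and MEF shares 0.980% ± 0.911, 0.452% ± 0.310 and 98.8% ± 0.674. Median UMIs per cell were 10864 and 12708 in the A2S day 6 libraries, 14853 and 16462 in ESCs and 19102 and 22796 in MEFs. Cells with under 1000 UMIs, left out, numbered 4 in A2S, 6 in S2 and 2 in AS at day 6, and 0 in the other groups compared here.

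**Figure D3:**
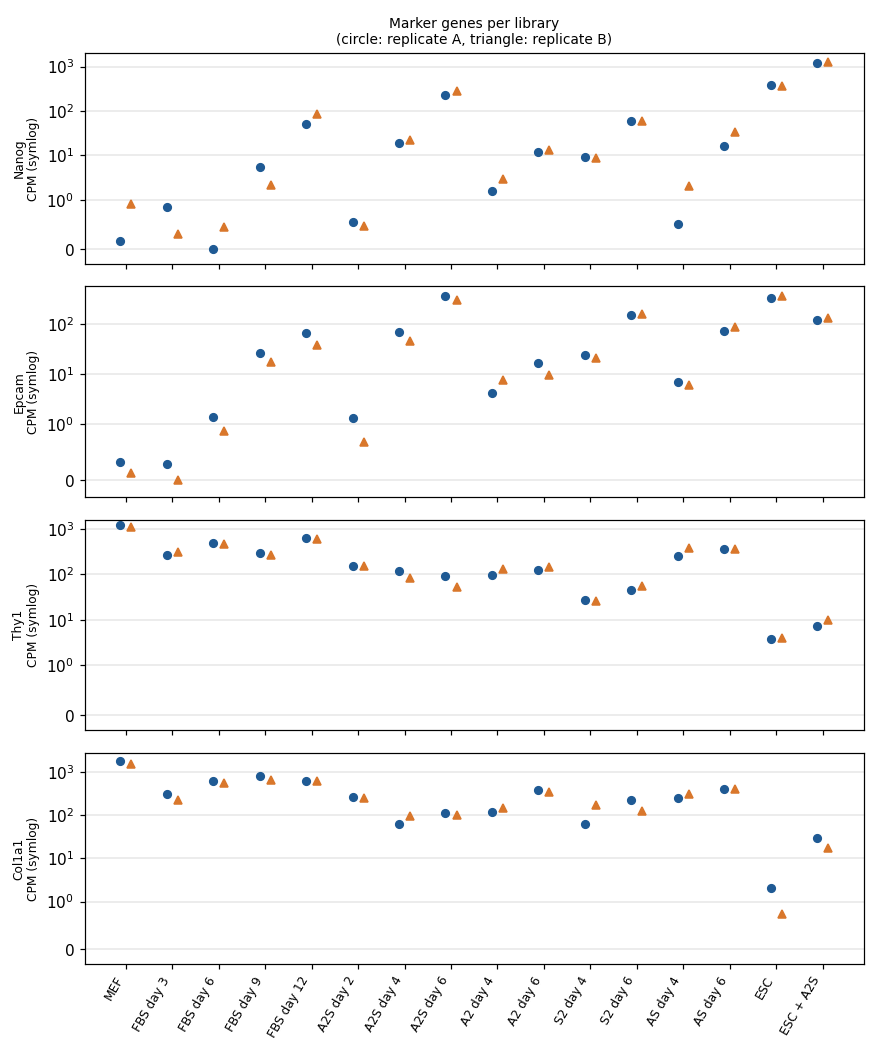
Levels of Nanog, Epcam, Thy1 and Col1a1 in CPM (axis linear near 0 and logarithmic above) for each of the 32 libraries, by group. Nanog and Epcam were near 0 in MEFs and high in A2S day 6 and both ESC groups, while Thy1 and Col1a1 were highest in MEFs.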

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

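The rule for data outside the comparisons, a share above 2 times that of the higher MEF library, was chosen after the data were seen, while the interaction tests were planned. Differences between day 4 and day 6 in the effect of an omission were called for 1047 genes in A2, 448 in S2 and 1440 in AS. Some other fits, listed with the interaction tests, called fewer. They gave 482 to 666 for A2, 128 to 243 for S2 and 665 to 942 for AS.

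FBS day 9, with 696 cells in no comparison, passed that rule in these lists, as % of UMIs against the higher MEF library: pluripotency at 0.157% against 0.0446%, epithelial at 0.0617% against 0.0167%, Wnt target at 0.107% against 0.0518%, keratinocyte at 0.12% against 0.0114%, macrophage and blood at 0.0146% against 0.00151%, endothelial at 0.0272% against 0.0125%, neural at 0.0888% against 0.0398% and erythroid at 4.26e-04% against 1.43e-05%. The 684 cells on the authors' feeder list passed it in these lists: pluripotency at 0.0993% against 0.0446%, epithelial at 0.0353% against 0.0167%, Wnt target at 0.133% against 0.0518%, interferon-response at 1.03% against 0.203%, germline at 0.00424% against 0.00211%, keratinocyte at 0.0443% against 0.0114% and macrophage and blood at 0.0805% against 0.00151%. The erythroid shares of FBS day 9 and of the MEF library rest on few UMIs. No explanation was tested for any of the shares above.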

How the results depend on the processing

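Comparisons among A2, S2 and AS were chosen after the data were seen, the other alternatives before. Counts of called genes stayed within 1.5 times under RLE factors, no count filter, listed cells kept and cells of 1000 UMIs or more. With DESeq2 the interactions called 666 genes for A2 and 942 for AS. In a fit of the compared groups alone, with fewer libraries to estimate the spread, AS day 4 had 1843 and the AS interaction 665. Leaving out 1 library, whose partner was then taken to vary like the other groups, gave 856 to 1371 for A2 day 4 against A2S day 4, 2701 to 3171 for A2 day 6 against A2S day 6, 285 to 532 for S2 day 4 against A2S day 4, 1060 to 1353 for S2 day 6 against A2S day 6 and 2487 to 3961 for AS day 4 against A2S day 4. The interactions gave 482 to 832 for the A2 interaction, 128 to 406 for the S2 interaction and 831 to 2106 for the AS interaction. The other comparisons stayed within that factor. Interferon-list members higher in AS day 4 ran from 4 to 32 of the 32 tested in those fits, and lists called for S2 from 1 to 6 at day 4 and 7 to 13 at day 6. The cause was not tested.

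For single genes named, leaving out each library in turn lost 68 calls and gained 11. DESeq2 lost 6 and gained 3, and keeping listed cells lost 9 and gained 5. With those cells kept, Col1a1 in A2S day 6 against ESC with A2S turned to -1.73 and Twist1 in ESC with A2S against ESC to 1.42. Without FBS day 12 B, Lyz2 from day 3 to day 12 turned to -0.88, against 4.33 without A. In AS day 4 against A2S day 4 its fitted value was -2.48 without AS day 4 B and 8.34 without A2S day 4 A, where a group was left with 0 UMIs, so neither is a fold. The cause was not tested. In the simulated A2 day 6 comparison, with far fewer changed genes than the real one called, 33.8% of 1.5-fold changes were called.

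With a correlation estimated for each list in place of the preset one, camera called fewer lists. It called 5 for A2S day 2 against MEF (13 preset), 10 for A2S day 6 against A2S day 2 (16 preset), 4 for FBS day 3 against MEF (11 preset) and 3 for FBS day 12 against day 3 (11 preset). Further counts were 6 for A2S day 6 against ESC with A2S (13 preset), 6 for FBS day 12 against ESC (14 preset), 9 for A2 day 6 against A2S day 6 (15 preset) and 0 for S2 day 4 against A2S day 4 (5 preset). Others were 3 for S2 day 6 against A2S day 6 (12 preset), 6 for AS day 4 against A2S day 4 (13 preset), 9 for AS day 6 against A2S day 6 (17 preset) and 5 for ESC with A2S against ESC (10 preset), with 7 for the A2 interaction (13 preset), 3 for the S2 interaction (6 preset) and 4 for the AS interaction (8 preset). For S2 day 4, 3 lists had an unadjusted p under 0.05 there.

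The replicate letters gave no pairing: same-letter deviations of 120 pairs of groups correlated at -0.318 to 0.270, with 13 above 0.1. With the letter as a block, counts of called genes ran from 829 for S2 day 4 against A2S day 4 to 9467 for ESC against MEF, all within 1.5 times, no count of called lists moved past that, and 1 gene named lost its call.

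Shares of cells with a UMI rose with depth. For Nanog they were 11.8% in A2S day 6, 4.27% in S2 day 6, 1.12% in AS day 6, 2.12% in FBS day 12, 11.9% in ESC and 38.9% in ESC with A2S at 500 UMIs. At 2000 UMIs they were 32.3% in A2S day 6, 1.46% in A2 day 6, 9.69% in S2 day 6, 3.24% in AS day 6, 5.90% in FBS day 12, 44.1% in ESC and 84.8% in ESC with A2S. Without thinning they were 48.8% in A2S day 6, 4.06% in A2 day 6, 23.7% in S2 day 6, 11.1% in AS day 6, 10.7% in FBS day 12, 85.5% in ESC and 96.5% in ESC with A2S. For Epcam they were 13.9% in A2S day 6, 0.190% in A2 day 6, 9.57% in S2 day 6, 3.06% in AS day 6, 2.12% in FBS day 12, 17.0% in ESC and 5.58% in ESC with A2S at 500 UMIs. At 2000 UMIs they were 43.1% in A2S day 6, 3.08% in A2 day 6, 25.5% in S2 day 6, 10.8% in AS day 6, 7.02% in FBS day 12, 51.2% in ESC and 21.1% in ESC with A2S. Without thinning they were 73.8% in A2S day 6, 10.2% in A2 day 6, 51.7% in S2 day 6, 26.1% in AS day 6, 13.9% in FBS day 12, 91.1% in ESC and 61.3% in ESC with A2S. Keeping listed cells gave 3.97% in FBS day 12 and 58.5% in ESC with A2S for Nanog and 4.22% in FBS day 12 and 9.46% in ESC with A2S for Epcam. Cells fell into 10 clusters at resolution 0.5 and 28 at 2.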

Other observations

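The tests of the Eif4a1 pattern, of a wrong label, of reads shared with an X copy and of Kdm5d were chosen after the result was seen, the other tests before, and the bound for the wrong label was loosened after its value was seen. From day 2 to day 6 with A2S, trophoblast genes had 8 of 12 higher and 0 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00394), with Tfap2c (7.64 ± 0.41) and Krt8 (ratio 119, 40.2 to 579.6). Keratinocyte genes had 7 of 11 higher and 1 lower (camera adjusted p = 0.0192, camera adjusted p = 0.0660 without A2S day 6 B), with Krt17 (at least 7.19-fold higher) and Lgals7 (at least 35.1-fold higher). Genes related to DNA and histone methylation had 13 of 26 higher and 1 lower (camera adjusted p = 0.00766, adjusted p = 0.114 with an estimated correlation), where Tet1 (5.00 ± 0.35) and Dnmt3b (2.30 ± 0.30) rose and Kdm2a (-0.56 ± 0.11) fell. Without the DOT1L inhibitor at day 6, trophoblast genes had 0 of 12 higher and 9 lower (camera adjusted p = 1.93e-05), with Esx1 (at least 8.83-fold lower). In ESCs with A2S against ESCs, imprinted genes had 2 of 22 higher and 14 lower (camera adjusted p = 9.19e-04), where Nnat (-5.73 ± 0.41) fell and Plagl1 (3.99 ± 0.28) and Peg13 (ratio 7.26, 2.27 to 37.1) rose. Neural genes had 5 of 22 higher and 13 lower (camera adjusted p = 0.00282), with Snap25 (at least 8.54-fold lower) lower and Nefm (4.62 ± 0.40) higher, and naive-state genes 10 of 15 higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.00334, adjusted p = 0.0537 with an estimated correlation). Between ESCs and MEFs, these methylation-related genes had 19 of 26 higher and 2 lower (19 and 3 adjusted over the list alone, camera adjusted p = 1.75e-04), with Mllt3 (-2.05 ± 0.21) and Tet3 (-1.53 ± 0.23) lower.

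Eif4a1 was at 22.5 to 29.4 CPM in the 6 A2S libraries and at 246 or more in all others. A response to the molecules is argued against by the Eif4a1 ratio of ESCs with A2S to ESCs, 0.970, as far as ESCs respond like fibroblasts. Counting against another reference, or fibroblasts of another genetic background, cannot be told apart. For the first, 48 genes differed over 4-fold the same way in all 6 comparisons, of which Raet1e, Eif4a1, Kcnf1, Acp1, Ccnb1ip1, C1qtnf3 and Dennd4c reached 10 CPM on both days, and for the second the highest A2S library had 1.30 times the Eif4a1 level of the lowest. A candidate explanation is therefore a difference in origin or processing between A2S and other libraries, which may add to the comparisons against A2S.

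Interferon-response genes were at 0.534% of UMIs in AS day 4 B and 0.195% in AS day 4 A. A minority of cells from another culture is argued against, since 85.2% of 236 cells of AS day 4 B (80.0 to 89.4, exact binomial) lay above the 95th percentile of AS day 4 A cells. A wrong label on an FBS day 3 library is argued against too, since 26.0% of 96 genes outside the list (17.6 to 36.0) that separate FBS day 3 from AS day 4 A were nearer to FBS day 3, although across 7687 genes AS day 4 B correlated at 0.956 with FBS day 3 A and 0.953 with AS day 4 A. Free RNA or cells of the feeder kind stay open, as the share in 24 listed cells was 1.96 times that of kept cells (1.49 to 2.61, bootstrap). The pattern is in 1 library, so no biological explanation was tested.

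Y-linked genes were lower in ESCs than in ESCs with A2S, with Eif2s3y at 37.3 ± 3.09 against 121 ± 18.7 CPM and Ddx3y at 18.9 ± 2.45 against 111 ± 0.373. Reads shared with the X copy are argued against, since Eif2s3x and Eif2s3y together were 2.32 times as high in ESCs with A2S as in ESCs. Loss of the Y chromosome as the whole cause is argued against by Kdm5d, with 0 UMIs in ESCs where 21.2 were expected at the Eif2s3y ratio. The excess of ESC cells without a Y-linked UMI over a Poisson share was 27.7% of 302 cells, against a median of 3.09% and a 95th percentile of 8.29% in 100 matched gene sets. Some ESC cells may thus have lacked a Y chromosome, a hypothesis that leaves the response of ESCs to A2S untested.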
